A study of Zea mays with 12 samples.

How the data were processed

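RNA-seq was performed on whole maize seeds of the inbred line Q319 (wild type) and of the transgenic line L100, collected 10 and 15 days after pollination (DAP). There were 4 groups of 3 libraries, 12 in all. Per the labels' protocols, seeds were frozen in liquid nitrogen, total RNA was extracted with CTAB, and libraries were made by standard Illumina protocols. Per the submitters' processing notes, Bowtie 0.12.2 and the B73 RefGen_v3 build were used. The program that quantified the reads, the annotation release, the strand setting and the filters are not given in the sources used here.

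Each deposited table listed 41430 gene models for 1 library, of which 2578 carried the name Maize_newGene; how these were made is not stated. The values analysed were the deposited expected counts per gene, which the authors wrote as whole numbers per the file headers. The deposited normalized signal was taken to be an unrounded estimate times 1 factor per library. This was inferred from the values, and how the factor was set is not stated. On that reading, 58.6% to 62.0% of the detected counts in each library equalled the unrounded estimate within 0.01. A further 37.3% to 39.4% lay above it by up to 1, and up to 2.7% by more. The signal served only to recover unrounded estimates for an added alternative. The deposited FPKM column was not analysed here. Totals ranged from 14014035 to 22370566 counts per library. The floor of 3 counts corresponded to 0.152 to 0.23 CPM (counts scaled to 1e+06 per library, after the TMM scaling described below). Floors and bounds cover counting error only.

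Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, genes were kept by filterByExpr, and a model with 1 mean per group was fitted to all 12 libraries by the robust quasi-likelihood method. Two-sided F tests on 24941 genes were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The 5 comparisons were L100 against wild type at 10 DAP and at 15 DAP, 15 DAP against 10 DAP in wild type and in L100, and the genotype by stage interaction, which is the genotype difference at 15 DAP minus that at 10 DAP. Log2 fold changes are given with their standard error (SE), and levels as TMM-scaled CPM with the standard deviation (SD) of 3 libraries. Where every library of a group held 0 counts, the fold was given as a lower bound against 3 counts per library. The labels do not say whether the libraries came from separate plants, so the p-values measure only the spread between these libraries. The tests, the thresholds, 26 gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

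Gene names came from a reference table of assembly Zm-B73-REFERENCE-NAM-5.0, used for names only. It matched 18021 models, 428 of them to more than 1 reference gene, and gave 2528 models a name other than a locus or clone code. The table held no product descriptions, so product patterns were applied to symbols and synonyms. The name su1 had no match, and some names matched more than 1 model or a synonym of another gene. Of the 26 lists, 3 had no match and 4 had fewer than 3 tested members. The remaining 19 were tested in 5 comparisons, 95 tests in all, with camera of limma 3.58.1 (preset correlation 0.01) adjusted over the 95 tests. The estimated correlation and fry were run beside it. A further 14 lists were chosen after the values could be seen and were adjusted in a family of their own.

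Genes were named by rule. Per comparison, among genes past the threshold with every library of one group above every library of the other and at least 5 CPM in the higher group, the rule took the 5 largest changes in each direction with an informative name, the 2 largest from each list, and the 2 largest in each direction regardless of name. For the interaction it took the 5 smallest p-values in each direction, and for genes changed at both stages the 5 with the largest smaller change in each direction. The starch and regulator genes sh2, bt2, bt1, sh1, wx1, ae1, o2 and pbf1 were named in the genotype comparisons whatever their result. The rule gave 115 distinct genes, of which a part is described. Genes outside it are said to have been chosen after their values were seen.

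Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, library totals without TMM, no filter, a filter of at least 5 CPM in 3 libraries, the replicate number as a block, a fit of the 2 groups compared alone, and leaving out each library in turn. Unrounded estimates, the omission of genome windows with many genotype calls, and the omission of list members with clashing names were added after the data were seen. The steps were tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. In the simulated comparison at 10 DAP, run on 24537 genes, 43% and 78% of these were recovered, and 1.6% of the calls were false. In the simulated comparison at 15 DAP, run on 24503 genes, 47% and 81% were recovered with 4.5% false calls. In that of the interaction, run on 24516 genes, 7% and 54% were recovered with 3.2% false calls. The simulated stage comparisons, run on 24541 genes in wild type and 24551 in L100, gave 5.3% and 7.3% false calls. Figures and tests on positions used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.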

Results

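Gene expression was compared in whole maize seeds of wild-type Q319 and of transgenic line L100 at 10 and 15 DAP, with 3 libraries per group. Of 24941 genes tested, 749 differed between the lines at 10 DAP and 1662 at 15 DAP. Between the stages 7836 genes differed in wild type and 6202 in L100, and 136 genes had a genotype by stage interaction.

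Stage was the largest axis of variation (36.4% of the variance) and genotype the second (20.9%). L100 10 DAP replicate 2 lay apart on the third axis (-73.5), and L100 10 DAP replicate 3 and L100 15 DAP replicate 3 lay apart on the fourth (65.9 and -71.2). L100 15 DAP replicates 1 and 2 were the closest pair within any group. Their chi-square per gene against counting error was 7, and that of the other pairs was 12.2 to 43.3. These 2 libraries may therefore be less independent than the others, and the labels do not settle it. Levels of replicates correlated at 0.962 to 0.968 and 0.953 to 0.968 in wild type at 10 and 15 DAP, and at 0.921 to 0.945 and 0.937 to 0.976 in L100. The 10 most abundant genes held 3.22% to 4.86% of the counts at 10 DAP and 11.67% to 16.56% at 15 DAP. Scaling by library totals instead of TMM moved the median log2 fold change of all genes by 0.07 and 0.09 in the genotype comparisons at 10 and 15 DAP. In the stage comparisons it moved the median by -0.32 in wild type and by -0.30 in L100. All changes are given on the TMM scale.

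At 10 DAP, some genes were expressed in one line and had 0 counts in the other. The gene AC218093.3_FG005 had 0 counts in all wild-type libraries and 64.6 CPM (SD 3.01, n = 3) in L100, at least 351-fold higher (adjusted p = 3.6e-05). GRMZM2G347270 had 0 counts and 55.9 CPM (SD 11.6), at least 303-fold higher (adjusted p = 0.00026). In the other direction GRMZM2G076387 went from 9.41 CPM (SD 2.07) in wild type to 0 counts in L100, at least 57.5-fold lower. The beta-carotene hydroxylase gene BCH2 was lower in L100 (log2 fold change -1.49, SE 0.15, adjusted p = 0.00028, 153 against 54.6 CPM). So were the plastid omega-6 desaturase gene fad6 (-1.57, SE 0.16, adjusted p = 0.00035, 151 against 50.9 CPM) and the basal layer gene bap-3b (-1.99, SE 0.30, adjusted p = 0.0063). The gene MFSP was higher (2.41, SE 0.28, adjusted p = 0.00079, 2.16 against 11.5 CPM). All of these calls were kept without any single library.

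In all, 439 genes were higher and 310 lower in L100 at 10 DAP, 295 and 172 of them by at least 2-fold. In 745 of the 749 the libraries of the lines did not overlap, which follows largely from selecting the genes on the same libraries. Of all tested genes 27.3% did not overlap, against 10% by chance. The count depended on single libraries. It was 305, 236 and 376 without wild type 10 DAP replicates 1, 2 and 3, 365 without L100 10 DAP replicate 2, and 1285 without L100 15 DAP replicate 3. The 2-fold count of 467 was 248, 197 and 310 without wild type 10 DAP replicates 1, 2 and 3, 277 without L100 10 DAP replicate 2 and 710 without L100 10 DAP replicate 3.

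At 10 DAP, the 13 genes of glycolysis and pyruvate phosphate dikinase lay lower in L100 as a list (median -0.40, mean -0.33, camera adjusted p = 0.011, adjusted p = 0.49 with an estimated correlation). Alone, 0 passed by edgeR, also when adjusted over the list alone. Of the 13, 5 were lower at an unadjusted p under 0.05, 2 by DESeq2 and 0 by voom. That list call ended without wild type 10 DAP replicate 2 (0.05). The 17 starch synthesis genes were not called as a list (median -0.22, camera adjusted p = 0.11, adjusted p = 0.63 with an estimated correlation). Of these genes 0 passed by edgeR, with 2 lower at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom. The list had an adjusted p of 0.048 without wild type 10 DAP replicate 1 and 0.00058 without L100 10 DAP replicate 1, and of 0.55 without L100 10 DAP replicate 2. In that library sh2 was at 279 CPM (647 and 596 in the other L100 libraries) and bt2 at 35.3 CPM (222 and 201). The 10 transfer layer genes were not called as a list (median -0.41, camera adjusted p = 0.065, adjusted p = 0.58 with an estimated correlation). That list had an adjusted p of 0.039 and 0.049 without replicate 2 of wild type at 10 and 15 DAP. The value was 0.0043 without L100 10 DAP replicate 1, and up to 0.44 without others. The list was called as lower once members with clashing names were left out. Individually, sh2 (-0.60, adjusted p = 0.24), bt2 (-0.57, 0.59), bt1 (-0.38, 0.63), sh1 (-0.01, 0.99), wx1 (-0.12, 0.91), the 2 models named ae1 (-0.57, 0.25; -0.41, 0.56), o2 (-0.85, 0.44) and pbf1 (-0.03, 0.94) did not pass. The sucrose transporter gene sut1 was higher in L100 (0.73, SE 0.15, adjusted p = 0.024, 64.7 against 107 CPM) and the endosperm bZIP gene ohp1 lower (-0.69, SE 0.11, adjusted p = 0.0085, 43.6 against 27.1 CPM). The call of sut1 ended without wild type 10 DAP replicate 1 (0.086) or 2 (0.12) or L100 10 DAP replicate 1 or 2 (0.068 each), and that of ohp1 without wild type 10 DAP replicate 2 (0.052).

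At 15 DAP, heat shock genes were lower in L100. The chaperone gene hsp101 fell from 1780 CPM (SD 1110) in wild type to 219 CPM (SD 90) in L100 (log2 fold change -3.02, SE 0.53, adjusted p = 0.01). The gene hsp22 fell from 1660 to 295 CPM (-2.49, SE 0.32, adjusted p = 0.0017). The 2 hsp70 genes fell from 852 to 184 CPM (-2.21, SE 0.31, adjusted p = 0.003) and from 3260 to 948 CPM (-1.78, SE 0.34, adjusted p = 0.012). The genes hsp101, hsp22 and hsp70 were chosen at this stage after their values were seen. The heat stress factor gene Hsf26 fell by 4.44 (SE 0.60, adjusted p = 0.0032, 130 against 5.96 CPM). Of the 9 heat shock genes, 8 passed as lower, 0 as higher and 1, hsp82, did not pass (2.04, adjusted p = 0.14); adjusted over the list alone, 8 were lower and 1 higher. The median was -2.21 and the mean -1.92, with camera adjusted p = 3.6e-07 and adjusted p = 0.43 with an estimated correlation. The list test kept its call without each library in turn (highest adjusted p = 8.8e-06). The count of 8 dropped to 5 without any wild type 10 DAP replicate or L100 15 DAP replicate 1, to 4 without wild type 15 DAP replicate 1 or 2 or L100 15 DAP replicate 3 and to 3 without L100 15 DAP replicate 2. The genes hsp101, hsp22, Hsf26 and the hsp70 gene GRMZM5G802801 kept their calls without each library in turn, and the call of the hsp70 gene GRMZM2G310431 ended without L100 15 DAP replicate 2 (0.055).

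**Figure D1:**
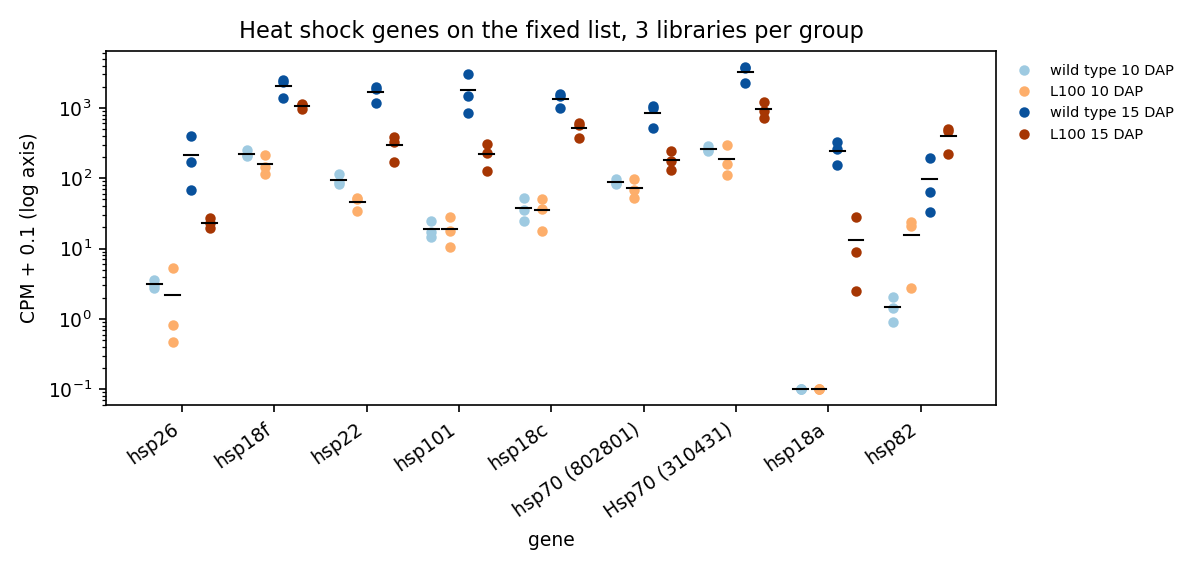
Levels of the 9 heat shock genes in each library (points; CPM plus 0.1 on a log axis, bars at the group means), for wild type and L100 at 10 and 15 DAP. At 15 DAP 8 genes were lower in L100 (hsp101, 1780 against 219 CPM) and hsp82 was not.

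The embryo globulin gene glb2 rose from 29.2 CPM (SD 9.71) in wild type to 526 CPM (SD 261) in L100 at 15 DAP (4.17, SE 0.67, adjusted p = 0.0073). This call was kept without each library in turn. The dehydrin gene dhn1 was also higher (3.02, SE 0.64, adjusted p = 0.021, 1.03 against 8.36 CPM). This call ended without wild type 15 DAP replicates 1, 2 or 3 (0.06, 0.066, 0.076) or L100 15 DAP replicates 2 or 3 (0.052, 0.054). Of 11 genes on the list of oil body, globulin and late embryogenesis proteins, 2 were higher, 0 lower and 9 did not pass, with 2 higher when adjusted over the list alone. The median was 0.87 and the mean 1.23, with camera adjusted p = 0.0066 and adjusted p = 0.43 with an estimated correlation. The list test stayed at or below 0.031 without each library. The count of 2 was 1 without wild type 15 DAP replicate 2 or 3 or L100 15 DAP replicate 2 or 3, and 4 without L100 10 DAP replicate 1. The allene oxide synthase gene aos2 was higher (4.59, SE 0.60, adjusted p = 0.0019, 0.343 against 8.36 CPM).

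The starch synthase gene du1 was lower in L100 at 15 DAP (-1.34, SE 0.26, adjusted p = 0.013, 533 against 211 CPM), also without each library in turn. The starch synthase gene ss1 was also lower (-0.86, SE 0.23, adjusted p = 0.042, 537 against 295 CPM). Without any library other than L100 10 DAP replicates 1 and 2 its call ended (highest adjusted p = 0.14). Of 17 starch genes 0 were higher, 2 lower and 15 did not pass, with 2 lower when adjusted over the list alone. The median was -0.34 and the mean -0.32, with camera adjusted p = 0.11 and adjusted p = 0.63 with an estimated correlation. The list had an adjusted p of 0.046 and 0.027 without L100 10 DAP replicates 1 and 2. The genes sh2 (-0.62, adjusted p = 0.2, 3370 against 2200 CPM), bt2 (-0.92, 0.34), bt1 (-0.63, 0.37), sh1 (-0.58, 0.34), wx1 (-0.43, 0.61), the models of ae1 (-0.57, 0.22; 0.71, 0.27), o2 (-1.35, 0.19; 305 against 120 CPM) and pbf1 (0.13, 0.67) did not pass. The endosperm factor genes ohp1 (-0.53, adjusted p = 0.02) and ohp2 (-0.42, adjusted p = 0.042) passed as lower. The call of ohp1 ended without wild type 15 DAP replicate 1 or 2 or L100 15 DAP replicate 2 or 3. That of ohp2 ended without any single library.

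The cytosolic glyceraldehyde phosphate dehydrogenase gene gpc3 was lower (-1.07, SE 0.20, adjusted p = 0.011, 1820 against 864 CPM). That call ended without L100 15 DAP replicate 2 (0.053). Of 13 glycolysis genes 0 were higher, 2 lower and 11 did not pass, with 5 lower when adjusted over the list alone. The median was -0.36 and the mean -0.43, with camera adjusted p = 0.0017 and adjusted p = 0.43 with an estimated correlation. The camera p stayed at or below 0.019 without each library. The count of 2 was 1 without any wild type 10 DAP replicate, wild type 15 DAP replicate 2 or 3, or L100 15 DAP replicate 1 or 3, 0 without L100 15 DAP replicate 2 and 4 without wild type 15 DAP replicate 1. The 5 zein genes did not pass at 15 DAP (median 0.30, mean 0.44, camera adjusted p = 0.5, adjusted p = 0.86 with an estimated correlation). The count was 0 by edgeR, 0 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by voom.

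**Figure D2:**
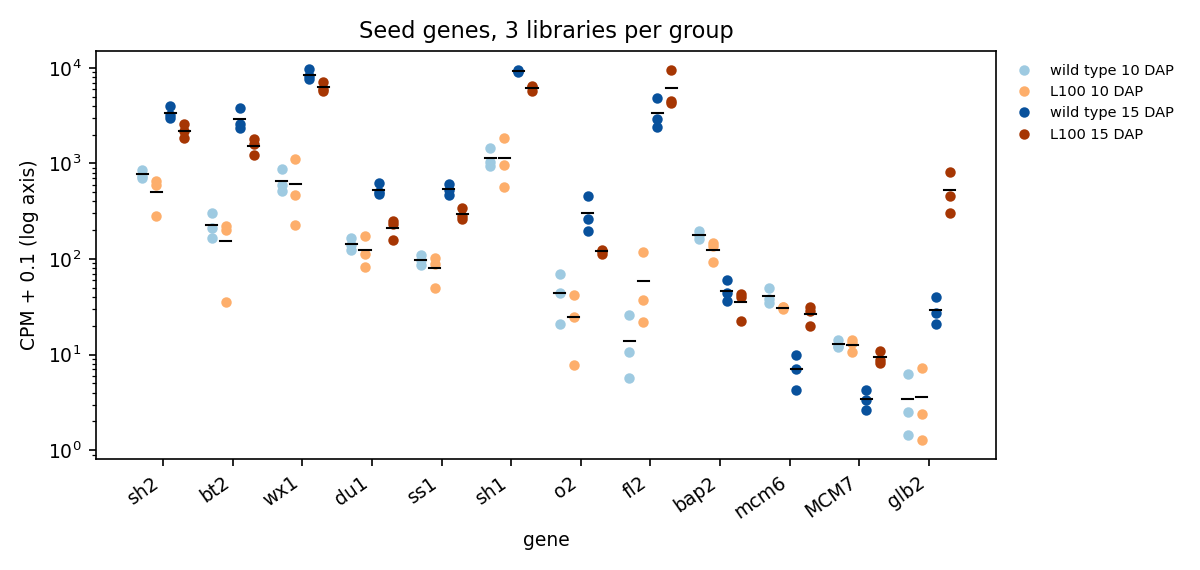
Levels of 12 seed genes in each library (points; CPM plus 0.1 on a log axis, bars at the group means), for wild type and L100 at 10 and 15 DAP. At 15 DAP du1 was lower in L100 (533 against 211 CPM) and glb2 higher (29.2 against 526 CPM).

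The DNA replication gene MCM6 was higher in L100 at 15 DAP (1.92, SE 0.27, adjusted p = 0.0029, 6.97 against 26.4 CPM). So were MCM7 (1.47, SE 0.21, adjusted p = 0.0029, 3.31 against 9.23 CPM) and pcna1 (1.12, SE 0.22, adjusted p = 0.013). The kinesin gene KIN6 was lower (-1.36, SE 0.27, adjusted p = 0.014). The genes pcna1 and KIN6 were chosen after their values were seen. Of the 9 genes of the list, 3 were higher, 1 lower and 5 did not pass, with 3 and 1 when adjusted over the list alone. The median was 0.21 and the mean 0.41, with camera adjusted p = 0.13 and adjusted p = 0.54 with an estimated correlation.

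At 15 DAP 891 genes were higher and 771 lower in L100, 624 and 321 of them by at least 2-fold. In 1648 of the 1662 the libraries of the lines did not overlap, which again follows largely from the selection. Of all tested genes 30% did not overlap, against 10% by chance. The count was 629 and 962 without wild type 15 DAP replicates 2 and 3 and 833 and 668 without L100 15 DAP replicates 1 and 2. The 2-fold count of 945 was 442 without wild type 15 DAP replicate 2, and 595 and 489 without L100 15 DAP replicates 1 and 2. With library totals 1156 genes were higher and 471 lower, so the balance between the directions depended on the scaling.

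At both stages, 158 genes were higher in L100 (15.7 by chance) and 77 were lower (9.6 by chance), while 7 and 3 changed in opposite directions. The gene GRMZM2G044438 rose from 0 counts in wild type to 15.6 CPM in L100 at 10 DAP, at least 84.9-fold higher, and from 0.0719 to 25.3 CPM at 15 DAP. Maize_newGene_1434 had 0 counts in wild type at both stages and 7.56 and 6.68 CPM in L100, at least 41-fold and 39.4-fold higher. GRMZM2G055143 was lower at both stages (-3.34, SE 0.42, adjusted p = 0.0015; -3.10, SE 0.41, adjusted p = 0.0019). The overlap of 235 genes was 129, 120 and 154 without wild type 10 DAP replicates 1, 2 and 3, and 137 and 144 without wild type 15 DAP replicates 2 and 3. It was 380 without L100 10 DAP replicate 3, and 143 and 141 without L100 15 DAP replicates 1 and 2. Over all tested genes the log2 fold changes of the stages correlated at 0.515 (Pearson) and 0.243 (Spearman).

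Many of these genes lay together on the chromosomes. In 18 of 207 windows of 10 Mb, the share of genes that differed at least 2-fold was 3 or more times the genome-wide share of 1.87% at 10 DAP or 3.79% at 15 DAP. Between 250 and 260 Mb of chromosome 1, 13.4% of the tested genes differed at 10 DAP and 14.6% at 15 DAP. Between 160 and 170 Mb of chromosome 8, 9.7% differed at 10 DAP and 4% at 15 DAP. Between 90 and 100 Mb of chromosome 10, 3.6% and 20.2% differed.

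**Figure D3:**
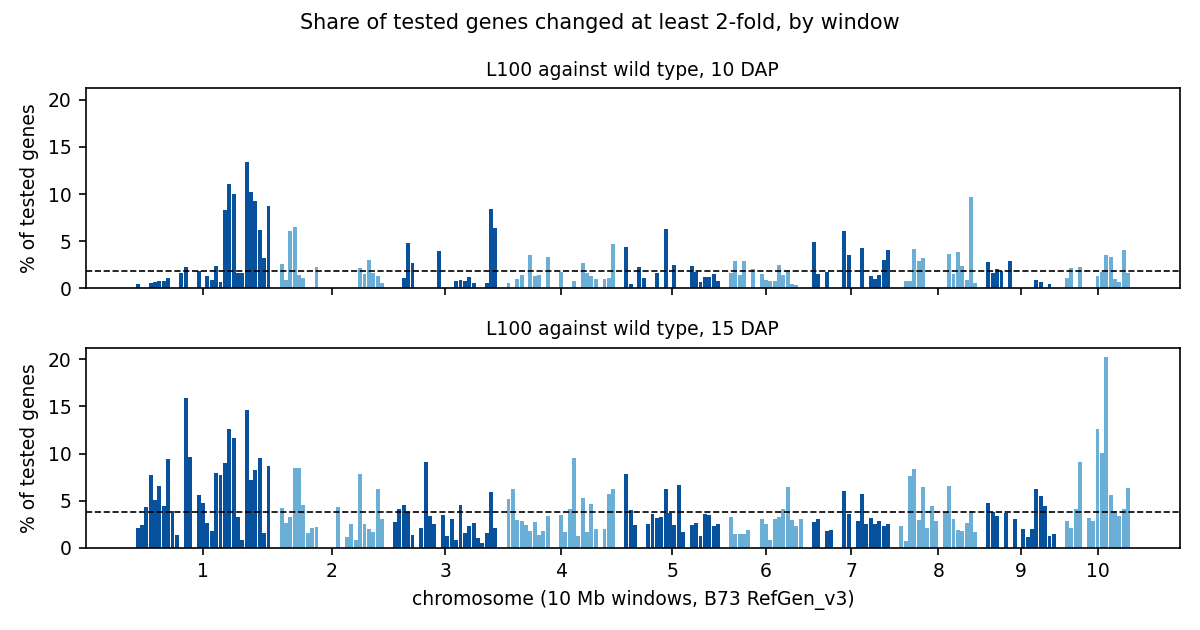
Share of tested genes changed at least 2-fold between L100 and wild type (percent, vertical) in 10 Mb windows along the 10 chromosomes (horizontal), at 10 DAP (top) and 15 DAP (bottom; dashed lines, 1.87% and 3.79% of all genes). Changed genes gathered in some windows, such as 250 to 260 Mb of chromosome 1 (13.4% and 14.6%).

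From 10 to 15 DAP, storage genes rose in both lines. In wild type the granule-bound starch synthase gene wx1 rose from 654 CPM (SD 185) to 8490 CPM (SD 1040; log2 fold change 3.70, SE 0.49, adjusted p = 3e-04). In L100 it rose from 601 to 6300 CPM (3.39, SE 0.48, adjusted p = 0.00066). The gamma-zein gene gz27 rose from 5210 to 50200 CPM (3.27, SE 0.47, adjusted p = 4e-04) and from 4400 to 59600 CPM (3.76, SE 0.48, adjusted p = 0.00029). The alpha-zein gene z1C2 (fl2) rose from 13.9 to 3360 CPM (7.92, SE 0.9, adjusted p = 0.00018) and from 58.8 to 6140 CPM (6.71, SE 0.85, adjusted p = 0.00048). The gene gz27, and bip1 and hsp101 in L100, were chosen after their values were seen. All 5 zein genes passed as higher in both lines, also when adjusted over the list alone. The medians were 3.27 and 3.76 (camera adjusted p = 0.00033 and 1.8e-05, adjusted p = 0.43 and 0.43 with an estimated correlation).

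Starch genes rose with them. In wild type 11 of 17 were higher, 0 lower and 6 did not pass, also 11 when adjusted over the list alone. The median was 0.98, with camera adjusted p = 0.00036 and adjusted p = 0.43 with an estimated correlation. In L100 9 were higher, 0 lower and 8 did not pass, 13 higher and 1 lower when adjusted over the list alone (median 0.85, camera adjusted p = 6.5e-05, adjusted p = 0.43 with an estimated correlation). Without L100 10 DAP replicate 3, 5 were higher. The ER chaperone gene bip1 (b-70) rose by 1.79 (SE 0.19, adjusted p = 6.2e-05) in wild type and by 1.19 (SE 0.19, adjusted p = 0.00098) in L100. In each line 5 of the 7 ER folding genes passed as higher, 0 as lower and 2 not, with 5 higher when adjusted over the list alone (medians 1.30 and 1.02, camera adjusted p = 0.0048 and 0.0048, adjusted p = 0.43 and 0.43 with an estimated correlation).

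Cell division and transfer layer genes fell in both lines. The cyclin gene cyc3 fell by 2.56 (SE 0.22, adjusted p = 2.2e-05) in wild type and by 2.57 (SE 0.22, adjusted p = 3.4e-05) in L100. Of the 9 DNA replication genes, 6 were lower in wild type, 0 higher and 3 did not pass, with 7 lower when adjusted over the list alone (median -1.94, camera adjusted p = 6.5e-05, adjusted p = 0.43 with an estimated correlation). In L100 5 were lower, 0 higher and 4 did not pass, with 6 lower when adjusted over the list alone (median -1.04, camera adjusted p = 0.00036, adjusted p = 0.43 with an estimated correlation). The gene bap2 fell by 1.94 (SE 0.26, adjusted p = 0.00031) and by 1.84 (SE 0.26, adjusted p = 0.00062). The gene bap-3b fell by 3.85 (SE 0.34, adjusted p = 2.7e-05) and by 4.70 (SE 0.40, adjusted p = 3.8e-05). Of 10 transfer layer genes 6 were lower, 1 higher and 3 did not pass in wild type, with 7 lower and 1 higher when adjusted over the list alone. The higher call ended without wild type 10 DAP replicate 1 or 3 or any wild type 15 DAP library. The median was -1.57, with camera adjusted p = 0.0012 and adjusted p = 0.43 with an estimated correlation. In L100 5 were lower, 1 higher and 4 did not pass, with 7 and 1 over the list alone (median -1.41, camera adjusted p = 0.035, adjusted p = 0.58 with an estimated correlation). The higher call ended without L100 10 DAP replicate 2 or 3 or L100 15 DAP replicate 2. The list call in L100 ended without wild type 15 DAP replicate 1 (0.054), L100 10 DAP replicate 1 (0.11) or L100 15 DAP replicate 2 (0.065).

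Heat shock genes rose at 15 DAP in both lines, hsp101 by 6.58 (SE 0.62, adjusted p = 6e-05) in wild type and by 3.55 (SE 0.54, adjusted p = 0.0012) in L100. The libraries carry no day label, so a rise with development cannot be told apart from conditions on the harvest day. All 9 genes passed as higher in each line, also when adjusted over the list alone, in wild type (median 5.18, camera adjusted p = 2.7e-08, adjusted p = 0.43 with an estimated correlation) and in L100. The median was 3.47, with camera adjusted p = 3.1e-07 and adjusted p = 0.43 with an estimated correlation. The small heat shock gene hsp18a had 0 counts at 10 DAP in both lines and 247 CPM at 15 DAP in wild type, at least 1340-fold higher, and 13 CPM (SD 13.2) in L100, at least 79.4-fold higher (34.2-fold without L100 15 DAP replicate 1). The embryo gene glb2 rose by 7.23 (SE 0.79, adjusted p = 0.00023) in L100 and by 3.15 (SE 0.69, adjusted p = 0.0068) in wild type. Of the 11 embryo genes 6 were higher in L100, 1 lower and 4 did not pass, with 6 and 1 when adjusted over the list alone (median 1.99, camera adjusted p = 0.022, adjusted p = 0.49 with an estimated correlation). The list call ended without L100 10 DAP replicate 3 (0.055), where 2 were lower, and 0 were lower without L100 10 DAP replicate 2. In wild type 4 were higher, 1 lower and 6 did not pass, with 6 and 1 when adjusted over the list alone, and the list was not called (median 1.15, camera adjusted p = 0.14, adjusted p = 0.58 with an estimated correlation). Without wild type 10 DAP replicate 1 or 3 or wild type 15 DAP replicate 2, 2 were higher. Without wild type 10 DAP replicate 2 or 3, wild type 15 DAP replicate 2 or 3 or L100 15 DAP replicate 2, 0 were lower. In wild type 4012 genes were higher and 3824 lower at 15 DAP, and in L100 3049 and 3153, with 1997 and 7374 and with 1795 and 7051 by library totals.

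The difference between the lines changed with stage for 136 genes, 68 in each direction. Maize_newGene_6786 was present in wild type at both stages (16.1 and 25.1 CPM) and in L100 at 15 DAP (30.1 CPM), against 0.306 CPM in L100 at 10 DAP, an interaction of 5.93 (SE 0.29, adjusted p = 2.8e-06). GRMZM2G133055 rose from 17.8 to 33.8 CPM in wild type and fell from 16.3 to 1.5 CPM in L100 (-4.35, SE 0.35, adjusted p = 0.00044). GRMZM2G133781 rose from 62 to 271 CPM in wild type against 71.3 and 42.6 CPM in L100 (-2.87, SE 0.32, adjusted p = 0.012). The interaction of glb2 was 4.08 (adjusted p = 0.093) and that of hsp101 -3.03 (adjusted p = 0.093), so neither passed (both chosen after their values were seen). As a list, the 9 heat shock genes had a lower interaction (median -1.46, camera adjusted p = 0.00061, adjusted p = 0.49 with an estimated correlation). It stayed at or below 0.005 without each library. Of its genes 0 passed by edgeR (4 lower when adjusted over the list alone, 6 lower at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom). The count of 136 was 30, 11 and 19 without wild type 10 DAP replicates 1, 2 and 3, and 53 and 13 without wild type 15 DAP replicates 1 and 2. It was 89, 23 and 220 without L100 10 DAP replicates 1, 2 and 3, and 23 and 17 without L100 15 DAP replicates 1 and 2.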

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

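The tests on dense chromosome windows (calls spread by chance, mixed haplotypes, mapping), on the harvest day and on the zein and embryo genes were chosen only after the result was seen, and so was the omission of list members with clashing names. The tests on other splits of the libraries, neighbouring copies, single libraries and an earlier developmental point were chosen before.

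The difference between the lines changed from 10 to 15 DAP, by the test of the interaction itself, for 136 genes. Of 60 splits drawn from the 200 possible, the real one included, only 1, the real one, gave as many genes. The highest other gave 18. Splits that mix the lines within a group carry the line differences in their spread, which lowers their calls. The comparison therefore cannot exclude chance for the count. The genes with the smallest p-values were Maize_newGene_6786 (5.93), GRMZM2G045239 (3.16), Maize_newGene_7558 (3.12), GRMZM2G056986 (3.05) and AC199541.4_FG007 (2.13) among those with a positive interaction on the log2 scale. With a negative one they were GRMZM2G133055 (-4.35), GRMZM2G178875 (-3.69), GRMZM2G133781 (-2.87), GRMZM2G011347 (-2.62) and GRMZM2G166944 (-1.94). The calls of GRMZM2G011347 and GRMZM2G166944 ended without wild type 10 DAP replicate 2 (adjusted p = 0.051 each). That of GRMZM2G045239 ended without wild type 10 DAP replicate 2 (0.051), wild type 15 DAP replicate 2 (0.055) or L100 10 DAP replicate 2 (0.054). The count was 11 without wild type 10 DAP replicate 2 and 220 without L100 10 DAP replicate 3, the lowest and highest. Without wild type 10 DAP replicates 1 and 3 it was 30 and 19, without wild type 15 DAP replicates 1 and 2 53 and 13. Without L100 10 DAP replicates 1 and 2 it was 89 and 23, and without L100 15 DAP replicates 1 and 2 23 and 17.

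Among genes named for their difference at 1 stage, the interaction also passed for aos2 (4.4, adjusted p = 0.042), MCM6 (2.33, adjusted p = 0.029), MCM7 (1.49, adjusted p = 0.049) and BCH2 (1.03, adjusted p = 0.05, just under the threshold before rounding). The call of MCM6 ended without wild type 10 DAP replicates 1, 2 or 3 (0.059, 0.055, 0.062), wild type 15 DAP replicate 2 (0.082), L100 10 DAP replicate 2 (0.06) or L100 15 DAP replicate 2 (0.078). That of MCM7 ended without any library other than wild type 15 DAP replicate 3 and L100 15 DAP replicate 3 (up to 0.12). That of aos2 ended without any library other than L100 10 DAP replicates 1 and 3 (0.056 to 0.11), and that of BCH2 without any other than L100 10 DAP replicate 1 (0.061 to 0.13). The DNA replication list had a higher interaction (camera adjusted p = 0.045, adjusted p = 0.43 with an estimated correlation). It ended at 0.053 without a member whose name matched the pattern by accident. It also ended without wild type 10 DAP replicate 1 (0.074), wild type 15 DAP replicates 1 and 2 (0.074, 0.069), L100 10 DAP replicates 1 and 3 (0.093, 0.055) or L100 15 DAP replicates 1 and 2 (0.069, 0.1). The heat shock list had a lower interaction (camera adjusted p = 0.00061, adjusted p = 0.49 with an estimated correlation).

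Genes that differed between the lines gathered in chromosome segments. Of the 15 windows dense at 10 DAP, 13 also lay above the genome-wide share at 15 DAP, as did 5 of the 6 dense at 15 DAP at the earlier stage. That is a lower bar than being dense, and how many of all windows cleared it was not counted. Only 3 of the 18 windows were dense at both stages. Some belonged to 1 stage, such as 70 to 80 Mb of chromosome 10 (1.3% at 10 DAP, 12.7% at 15 DAP). The number of calls per 10 Mb window varied 3.17 times as much as in shuffled calls at 15 DAP and 5.18 times at 10 DAP (permutation test, p = 0.0001, the smallest that 10000 shuffles can give), and still 1.94 and 2.90 times when 1 called gene was kept per 0.2 Mb, which argues against chance and against neighbouring copies that share reads as the whole cause. Nearby genes shared the odd library more than genes of different chromosomes in L100 (excess squared correlation 0.065 at 10 DAP and 0.097 at 15 DAP), against 0.114 and 0.087 in wild type, so the criterion that L100 exceed both wild-type groups was not met and the test does not set L100 apart. There were 86 genes under 0.1 CPM in both wild-type groups and at 1 CPM or more in both L100 groups, and 18 the other way, which may reflect absent genes, expression or reads of one haplotype that did not map; counts alone cannot tell these apart. A candidate explanation is that L100 carries chromosome segments of another parent, which the sources used here do not describe and which was not tested against genotypes.

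At 15 DAP, 8 of the 9 heat shock genes were lower in L100, with a list median of -2.21 (camera adjusted p = 3.6e-07, adjusted p = 0.43 with an estimated correlation). The count of 8 was 3 without L100 15 DAP replicate 2, and 4 or 5 without any other library except wild type 15 DAP replicate 3 and the L100 10 DAP libraries, while the list test stayed past its threshold without each library in turn (highest adjusted p = 8.8e-06), which argues against a single library as the cause of the list result. Another 174 genes had as large a rise from 10 to 15 DAP in wild type. At 15 DAP they were lower in L100 by a median of -0.67 (117 of 174 lower). That value lies between the limits set for and against an earlier developmental point. The choice of these genes from the same wild-type libraries pushed it down. Its bootstrap 95% interval, -0.86 to -0.37, was drawn over genes, so it leaves out the spread between libraries. Temperature or handling on the harvest day could have differed between the lines or between the stages. It cannot be told apart from genotype or stage, because no library carries a day or batch label. An effect of the genotype itself also stays open.

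At 15 DAP embryo genes were higher in L100 as a list, while heat shock genes were lower (adjusted p = 0.43 with an estimated correlation for each). In both lines the heat shock genes were higher at 15 DAP than at 10 DAP. Whole L100 seeds may have been behind in development, in which case zeins should have been lower; the mean of 17 zein genes was instead 0.83 higher (SE 0.17, 2 of 17 passed, 1 without any wild type 10 DAP library and 0 without wild type 15 DAP replicate 2 or 3 or any L100 15 DAP library, list median 0.52, camera adjusted p = 0.0016, adjusted p = 0.65 with an estimated correlation), and the median of the 5 zein genes fixed before was 0.30. At 10 DAP the mean difference of the same 17 genes was 0.47 (SE 0.65, list median 1.39). It was -0.08 without L100 10 DAP replicate 1, so 1 library set its sign. The alpha-zein family, also tested as a list, had a median of 1.9 at that stage. Its camera call ended without wild type 10 DAP replicate 1 (adjusted p = 0.11) or L100 10 DAP replicate 1 (0.23). A standing difference between the lines was thus not established. The change of the mean difference from 10 to 15 DAP was 0.35 (SE 0.67, lower limit -0.99; -0.05 without L100 10 DAP replicate 1, and -1.86 to -0.74 without any other library), but the list median of the interaction was -0.57 with 11 of 17 negative (camera adjusted p = 0.9, adjusted p = 0.95 with an estimated correlation), which leaves a delay open, although the limit set for excluding it, a zein median of 0 or above, was met, because that limit took no account of the level at 10 DAP, which the libraries left uncertain. Other genes that changed with stage went both ways at 15 DAP. MCM6 and MCM7, which fell with stage in wild type, were higher in L100, and du1, which rose, was lower, as a delay would predict. The gene glb2 also rose but was higher in L100. These genes were named for their differences in the same data, so they do not decide on a delay. A larger share of embryo might explain the embryo genes (median 0.87, camera adjusted p = 0.0066, adjusted p = 0.43 with an estimated correlation), so this stays open too, and a change of expression within the embryo was not tested.

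For the other comparisons the 6 libraries make 10 splits, too few for a share under 0.05. Here too, splits that mix the lines or stages within a group carry the differences in their spread, which lowers their calls. The low counts of the other splits are therefore no measure of chance. The real split, 1 of the 10 in each, gave 749 genes for the lines at 10 DAP (highest other 3), 1662 at 15 DAP (highest other 1), 7836 for the stages in wild type (highest other 2) and 6202 in L100 (highest other 75).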

How the results depend on the processing

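The alternatives with unrounded estimates, without genes in windows dense in genotype calls (windows selected on the outcome), and without clashing list members were chosen after the data were seen. Of 3760 values of named genes under an alternative, 3502 kept their side of the threshold. The sign turned in 12, those of 3 genes at 10 DAP (wx1, sh1 and pbf1), which passed in none of them. The cause was not tested for any change below, except that fewer genes or libraries were tested outside the dense windows and without single libraries.

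At 10 DAP (749 genes; 467 at least 2-fold) DESeq2 gave 2006 (975), the replicate block 390 (282), the genes outside dense windows 477 (274) and single omitted libraries 236 to 1285 (197 to 710). At 15 DAP (1662; 945) DESeq2 gave 2889 (1477), the block 1073 and single omitted libraries 629 to 1871 (442 to 1094). Between stages in L100 (6202) a fit of the 2 groups alone gave 4094. For the interaction (136; 121) DESeq2 gave 1081 (678), voom 65 (61), library totals 74 (71), the block 26 (26) and single omitted libraries 11 to 220 (11 to 206). For the overlap (235) these were 555 by DESeq2, 138 with the block, 120 with 2 groups alone, 116 outside dense windows and 120 to 380 without single libraries. DESeq2 called 746 of the 749 and 1656 of the 1662 genes. On simulated counts at 15 DAP 20.9% of its calls were false against 4.5% for edgeR. Those counts held 100 genes changed 2-fold and 100 changed 4-fold, far fewer than were called here. The false shares therefore do not carry over to the real calls. Replicate numbers did not pair libraries (residual correlation -0.106 to 0.044 for equal numbers), so the block had no basis in the data.

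Of 95 list tests 20 passed, 0 with an estimated correlation (9 at an unadjusted p under 0.05), 29 by fry, 21 without clashing names, and 18 to 25 without single libraries. Without clashing names 1 call was lost and 2 were gained, the embryo list in the interaction (0.035) and the transfer layer list, lower in L100 at 10 DAP (0.021). Library totals split the genes at 15 DAP into 1156 higher and 471 lower, and turned the sign of the median of the endosperm factors (0.29 to -0.03), glycolysis (0.10 to -0.21) and ethylene (0.21 to -0.11) lists between stages in wild type, and of sucrose genes at 15 DAP (-0.08 to 0.01). The same held for abscisic acid genes (0.07 to -0.24) between stages in L100, where the trehalose gene went from 0 to -0.31, and for fatty acid (-0.02 to 0.05) and seed protease (-0.07 to 0.01) genes at 10 DAP. The 2-group fit gives no interaction, and the alternatives for normalized values were not run because the files hold counts. Per library, 3 counts are 0.152 to 0.23 CPM, below which no fold is given, and on simulated counts 7% of 2-fold interactions were recovered.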

Other observations

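The gene lists and genes in this part were chosen after the data were seen, and they were adjusted apart from the lists fixed before.

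The lipoxygenase gene lox3 was higher in L100 by 1.44 at 10 DAP (SE 0.22, adjusted p = 0.005) and by 1.26 at 15 DAP (SE 0.22, adjusted p = 0.0072, 80 against 191 CPM), with an interaction of -0.18 (adjusted p = 0.82). The oxophytodienoate reductase gene opr7 was higher by 0.83 (SE 0.11, adjusted p = 0.002, 29.9 against 53.1 CPM) and by 0.85 (SE 0.11, adjusted p = 0.0016, 28.1 against 50.7 CPM). Both kept their calls without each library in turn. As a list, 2 of 23 lipoxygenase and allene oxide synthase genes were higher at 10 DAP, 0 lower and 21 did not pass, with 4 higher when adjusted over the list alone. The median was 0.52, with camera adjusted p = 0.00095 and adjusted p = 0.51 with an estimated correlation. At 15 DAP 3 were higher, 0 lower and 20 did not pass. The median was 0.07, with camera adjusted p = 0.44 (0.039 without L100 15 DAP replicate 3, and up to 0.84 without others) and adjusted p = 0.79 with an estimated correlation.

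The aquaporin gene NIP3-1 was higher at 10 DAP (0.96, SE 0.13, adjusted p = 0.003, 73.3 against 142 CPM) and 15 DAP (0.87, SE 0.14, adjusted p = 0.0041, 24.4 against 44.7 CPM). TIP4-1 was higher at 15 DAP (2.37, SE 0.42, adjusted p = 0.0082, 1.44 against 7.5 CPM). The aquaporin family was mixed at 15 DAP, with 5 genes higher and 3 lower in L100 (list median 0.15). Without single libraries 2 to 5 were higher and 0 to 3 lower. The cytokinin oxidase gene CKX5 was lower at 15 DAP (-1.82, SE 0.18, adjusted p = 0.00029, 54.3 against 15.4 CPM). The chaperone gene HSP90-1 was lower at 15 DAP (1070 against 133 CPM, adjusted p = 0.0029). So were HSP90-2 (-1.20, SE 0.17, adjusted p = 0.0029) and the heat stress factor gene Hsf03 (-2.84, SE 0.38, adjusted p = 0.002, 24.8 against 3.46 CPM). Of 26 heat shock genes and factors 15 were lower at 15 DAP, 0 higher and 11 did not pass, with 16 lower and 2 higher when adjusted over the list alone (median -1.07, camera adjusted p = 3.8e-08, adjusted p = 0.41 with an estimated correlation). The count was 10 to 15 without single libraries.

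Ribosomal protein genes were lower in L100 at 10 DAP as a list of 26 (median -0.33, camera adjusted p = 9.9e-06, adjusted p = 0.59 with an estimated correlation). Of its genes 0 passed by edgeR (1 lower when adjusted over the list alone, 12 lower at an unadjusted p under 0.05, 6 by DESeq2 and 0 by voom). From 10 to 15 DAP in wild type 17 of them were lower, 1 higher (0 without wild type 10 DAP replicate 1 or 3) and 8 did not pass. The median was -0.66, with camera adjusted p = 2.3e-05 and adjusted p = 0.61 with an estimated correlation. In L100 7 were lower and 3 higher (median -0.25), and 13 were lower without L100 15 DAP replicate 3. Between the lines at 15 DAP the list median was 0.03, and that of the interaction was 0.3. All 17 zein genes rose in wild type (camera adjusted p = 7.4e-12, adjusted p = 0.37 with an estimated correlation), and 16 in L100 (1.7e-15, adjusted p = 0.26 with an estimated correlation). At 15 DAP the summed TMM-scaled CPM of the zeins, written as a percentage, was 10.62%, 10.38% and 8.02% in the wild-type libraries. In the L100 libraries it was 11.03%, 11.09% and 16.02%. These percentages include the TMM scaling, so they are not shares of the counts.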
